A study of Mus musculus with 38 samples.

How the data were processed

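The series holds 38 RNA-seq libraries of mouse mPFC, made by translating ribosome affinity purification. Per the labels' protocols, polysomes were immunoprecipitated from mPFC homogenates in the presence of cycloheximide with monoclonal antibodies against EGFP. RNA was purified with a column kit, cDNA was amplified with the NuGEN Ovation V2 kit, and libraries were sequenced on a NextSeq 500. For the first experiment (16 libraries) wild-type mice had received a retrograde virus carrying EGFP-Rpl10a in the AHNc 1 month before dissection, per the labels. For the second (22 libraries) mice carrying Cacna1h-Cre and the EGFP-Rpl10a reporter were used.

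The authors deposited 1 file per library with raw counts per gene for 24100 genes, each with an NCBI Gene ID and a symbol. The values are whole numbers with a different total in each library, and no normalization was found in them. The submitters' processing notes list STAR 2.3.0e, HTSeq, DESeq2 1.34.0 and the build mm10, without a role or an order, and the file names carry the word subread. The annotation version, the strand setting and any filter are not stated, so counts of overlapping and antisense genes, and of near-identical gene copies such as the globin, heat shock and ribosomal protein genes with their pseudogenes, are uncertain. No mitochondrially encoded gene is in the files. Of the 24100 IDs, 24045 matched the reference table of GRCm38, from which chromosomes and positions were taken. A further 9 IDs have no symbol in the files, and 0 of these matched.

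Samples were grouped by experiment, sex, estrous stage and fraction as the sample titles give them. The 5 female AHN mice form 1 group, because replicate numbers 1 and 2 occur more than once among them. The column headers of 7 files of Met and Pro libraries give another stage than the titles, and the titles were used. Same-numbered IP and input libraries of the Cacna1h experiment come from the same mouse by the design text. Deviations of same-numbered libraries from their group means correlated at -0.0138 to 0.15 over the 11 Cacna1h pairs. In a stage of 2 mice both pairs have the same correlation by construction, so these are 7 separate values, of which that of Pro was negative. The 3 male pairs each matched best with their own number. Fits with a block for the replicate were run as an alternative. The p-values of comparisons between libraries measure the spread between animals as the labels give them. Permutations and binomial intervals over genes take genes as units, which are not independent, and counting floors cover counting error only.

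Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr on the groups of each fit, glmQLFit with robust estimation and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p, all two-sided. IP was compared with input as the mean over sexes (AHN) or over males and the 4 stages (Cacna1h). The sexes were compared within IP and within input, and an interaction tested whether the sex difference differed between fractions. Stages were compared by an F test of equality of Di, Met, Es and Pro with the males included for the spread, followed by Es against Di and each stage against males. The difference of the enrichments of both experiments was tested in a fit of all 38 libraries in 14 groups. With 2 libraries per stage, the spread of each stage is assumed to be that of the other groups.

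These designs, 38 gene lists, the rule for naming genes and the alternatives listed at the end of this section were fixed before the data were examined. Alternatives added after the data were seen are named where all alternatives are compared. The rule takes, from genes past the threshold with every library of one side above every library of the other (not required for the stage test) and a mean of at least 1 CPM, the 12 with the highest and the 12 with the lowest fold change, and leaves symbols of predicted genes unnamed. It adds up to 4 members of each list by smallest p and a fixed set of 17 genes (among them Cacna1h, Cacna1g, Cacna1i, Rpl10a, Esr1, Esr2, Pgr, Oxtr, Avpr1a, Crh, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty). Results of some of the genes chosen in these ways are not reported here. Malat1 was singled out after its values were seen. Lists with at least 3 measured genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of each comparison, and again with an estimated correlation. Of 259 list tests 60 passed with the preset correlation and 7 with an estimated one, and these 7 were lists of Y-linked genes and of X inactivation and escape genes between the sexes. Camera could not be applied to the stage F test.

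The procedure was tested on simulated counts with known changes. For AHN IP against input it recovered 66% of genes changed 2-fold and 90% of those changed 4-fold, with 6.02% false calls, and for Cacna1h IP against input 66% and 91%, with 5.99%. The shares were 32% and 81% for the sexes in AHN IP, 14.1% and 65.3% for the sexes in Cacna1h IP, 10% and 63% for the stage test and 11% and 61% for Es against Di, with 7.38%, 3.70%, 13.1% and 12.2% false calls. The alternatives tried were DESeq2 1.42.0 in place of edgeR, RLE in place of TMM factors, no filter on low counts, the replicate block, wider or narrower sets of libraries in the fit, a 2-fold minimum and each library left out in turn. Regrouped libraries were counted against the real groups. The 40 pairs of replicates differed by 13.3 to 281 times the chi-square of counting error, so neither library of these pairs was a copy of the other. No library was left out of the comparisons.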

Results

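Ribosome-bound RNA was isolated from the mouse medial prefrontal cortex (mPFC) by translating ribosome affinity purification, in which ribosomes carrying the EGFP-tagged protein Rpl10a are pulled down with antibodies against EGFP. Each pull-down (IP) was accompanied by libraries of total RNA from the same kind of tissue (input). The first experiment tagged mPFC neurons that project to the AHN, the region in which a retrograde virus carrying EGFP-Rpl10a had been injected, in wild-type mice. It comprised 3 male and 5 female IP libraries and as many inputs. The second experiment tagged cells by a Cre line for Cacna1h, the gene of the T-type calcium channel Cav3.2, crossed to an EGFP-Rpl10a reporter. It comprised 3 male IP libraries, 2 female IP libraries from each of the estrous stages labelled Di, Met, Es and Pro (diestrus, metestrus, estrus and proestrus), and as many inputs. Total counts per library ranged from 25001916 to 40934740 in the AHN IP libraries and from 33359079 to 43268524 in the AHN inputs. They ranged from 7981647 to 15282996 in the Cacna1h IP libraries and from 11248698 to 15413608 in the Cacna1h inputs. In the shallowest library, Es IP replicate 10, 1 count corresponds to 0.125 CPM before TMM scaling. Levels are given as mean CPM ± SD over libraries with the TMM factors of the fit at hand. Levels of single libraries use factors over all libraries of an experiment, so the 2 kinds of level can differ by a few percent. The adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. In the mouse build GRCm38, Cacna1h (gene ID 58226 in the files) lies on chromosome 17 from 25374285 to 25436334 and Rpl10a (19896) on chromosome 17 from 28328471 to 28331033. Rgs5 (19737) lies on chromosome 1 from 169655501 to 169695813 and Drd2 (13489) on chromosome 9 from 49340360 to 49408177.

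The first question was which transcripts are over-represented on the ribosomes of AHN-projecting neurons against the whole mPFC. The AHN pull-downs carried more RNA of excitatory neurons and less of glia and of several interneuron genes. Slc17a7, which encodes the vesicular glutamate transporter VGLUT1, stood at 984 ± 115 CPM in IP (n = 8) and 577 ± 97.8 CPM in input (n = 8), a log2 difference of 0.82 (SE 0.10, adjusted p = 2.2e-06). Genes of the pyramidal tract neurons of layer 5, the cortical cells whose axons leave the cortex for subcortical targets, were higher as well. Among them were Bcl6 (log2 0.86, SE 0.13) and Chst8 (14.5 ± 6.05 CPM in IP, 5.69 ± 0.642 CPM in input). The oligodendrocyte gene Mog was at 6.35 ± 2.12 CPM in IP and 29.0 ± 3.76 CPM in input, and Tyrobp, a signalling adaptor of microglia, at 2.83 ± 1.31 CPM and 32.7 ± 9.46 CPM. Of 16858 genes tested, 6039 passed an adjusted p of 0.05, of which 3074 were higher and 2965 lower in IP. Of these, 337 were at least 2-fold higher and 1555 at least 2-fold lower.

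Of the 12 pan-excitatory genes tested, 9 rose and 0 fell (10 adjusted over the list alone), with a median log2 difference of 0.517 and a camera adjusted p of 1.11e-04 (adjusted p = 0.337 with an estimated correlation). Of the 12 genes of layer 5 pyramidal tract neurons, 9 rose and 0 fell (10 adjusted over the list alone), with a median of 0.595 and a camera adjusted p of 6.36e-04 (adjusted p = 0.337 with an estimated correlation). Genes of other cortical projection classes were not uniformly higher. In layer 5 intratelencephalic neurons, whose axons stay within the telencephalon, 1 of 8 genes rose and 4 fell (5 adjusted over the list alone, camera adjusted p = 0.169). Among 10 genes of layer 6 corticothalamic neurons, 1 rose and 4 fell (6 adjusted over the list alone, camera adjusted p = 0.169). Hs3st4 had a log2 difference of -0.98 (SE 0.12, adjusted p = 2.98e-06) and the neurotensin receptor gene Ntsr1 at 1.04 (SE 0.31, adjusted p = 0.0109). Among 11 upper-layer genes, 3 rose and 3 fell (7 adjusted over the list alone, camera adjusted p = 0.841). Wfs1, an endoplasmic reticulum gene, rose from 113 ± 12.1 to 325 ± 142 CPM.

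Several interneuron genes were lower in the AHN pull-downs. Pvalb, the calcium buffer of fast-spiking interneurons, was at 5.05 ± 1.30 CPM in IP and 22.2 ± 3.37 CPM in input (log2 -2.17, SE 0.18, adjusted p = 3.54e-08). The neuropeptide gene Vip was at 8.37 ± 3.41 and 29.7 ± 3.80 CPM (log2 -1.87, SE 0.22, adjusted p = 1.34e-06). Of 12 pan-GABAergic genes 0 rose and 7 fell (8 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.432 with an estimated correlation). Of 11 genes of Vip, Lamp5 and Sncg interneurons 0 rose and 6 fell (6 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.337 with an estimated correlation). Glial lists were lower as well. All 14 microglial genes fell (14 adjusted over the list alone, median log2 -1.83, camera adjusted p = 1.63e-07). So did 12 of 13 oligodendrocyte genes (12 adjusted over the list alone, median -1.42, camera adjusted p = 1.05e-06) and 11 of 14 astrocyte genes (12 adjusted over the list alone, median -0.885, camera adjusted p = 4.4e-05). With an estimated correlation the adjusted p of these lists was 0.337, 0.337 and 0.355. Of 9 fibroblast and meningeal genes 5 fell (5 adjusted over the list alone, median -1.40, camera adjusted p = 0.00909, adjusted p = 0.355 with an estimated correlation). Of 16 endothelial and mural genes 4 fell and 0 rose (4 adjusted over the list alone, camera adjusted p = 0.159).

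Nptx2, a secreted synaptic pentraxin induced by activity, was among the genes with the largest increase, at 92.3 ± 31.8 CPM in IP and 18.3 ± 5.77 CPM in input (log2 2.38, SE 0.21, adjusted p = 5.98e-08). The neurotrophin gene Bdnf rose by a log2 of 1.12 (SE 0.15, adjusted p = 7.85e-06). Of 21 activity-regulated genes 14 rose and 0 fell (15 adjusted over the list alone, median 0.483, camera adjusted p = 1.48e-05, adjusted p = 0.337 with an estimated correlation). Other genes with the largest increases were Dlk1, a Notch-family ligand (47.8 ± 24.9 against 8.57 ± 4.79 CPM), and P2rx5, an ATP-gated channel (log2 2.48, SE 0.48). Further ones were Crabp2, a retinoic acid binding protein (log2 2.44, SE 0.45) and the pacemaker channel gene Hcn4 (5.36 ± 2.26 against 1.16 ± 0.763 CPM). Pcdh8, a protocadherin, rose by 1.78 (SE 0.14, adjusted p = 9.76e-09). Among the genes with the largest decreases were Ccl5, a chemokine (2.33 ± 1.29 against 30.2 ± 14.6 CPM), and Cdr1, known for a circular RNA (227 ± 109 against 2288 ± 542 CPM). Of 82 genes of cytosolic ribosomal proteins 2 rose and 46 fell (50 adjusted over the list alone, median -0.479, camera adjusted p = 1.63e-07, adjusted p = 0.550 with an estimated correlation). Rpl4, for instance, had a log2 difference of -0.75 (SE 0.09).

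Channels and hormone receptors were followed because the series concerns reproductive state. Cacna1h itself rose in AHN IP from 28.3 ± 4.38 to 47.9 ± 7.0 CPM (log2 0.79, SE 0.12, adjusted p = 3.89e-05), in every IP library above every input. The other T-type channel genes Cacna1i and Cacna1g rose by 0.82 (SE 0.12) and 0.34 (SE 0.13, adjusted p = 0.0452), and Cacna1e, an R-type channel, by 1.03 (SE 0.13). Of the fits that left out 1 library, 6 of 16 called Cacna1g. Of 21 voltage-gated calcium channel genes 10 rose and 4 fell (16 adjusted over the list alone, camera adjusted p = 0.0533). The oxytocin receptor gene Oxtr rose from 8.67 ± 2.15 to 15.3 ± 7.76 CPM (log2 0.86, SE 0.25, adjusted p = 0.0117), and the progesterone receptor gene Pgr fell by 0.36 on the log2 scale (SE 0.13, adjusted p = 0.0325). Leaving out female IP replicate 1 (library 3085) or 2 (library 3086), female input replicate 3, male IP replicate 2 or 3 or male input replicate 1 ended the call of Pgr. The oestrogen receptor gene Esr1 (9.09 ± 2.94 against 6.33 ± 2.54 CPM) did not pass, at an adjusted p of 0.102.

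Rpl10a, the gene of the tagged protein, stood at 389 ± 190 CPM in AHN IP and 61.9 ± 21.4 CPM in input (log2 2.66, SE 0.44, adjusted p = 3.4e-04). Counts of the endogenous gene and of the virus cannot be separated. One pull-down did not carry it: female IP replicate 3 (library 3087) had 34.6 CPM, against 285 to 643 CPM in the other 7 IP libraries. Its same-numbered input (library 3084) had 31.1 CPM, the lowest of the 8 inputs, with 41.6 and 42.1 CPM in female inputs 3082 and 3083. Library 3087 also had the highest share of the nuclear RNA Malat1 among the AHN IP libraries, 1.21% of counts. Without libraries 3084 and 3087, 7268 genes passed.

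**Figure D1:**
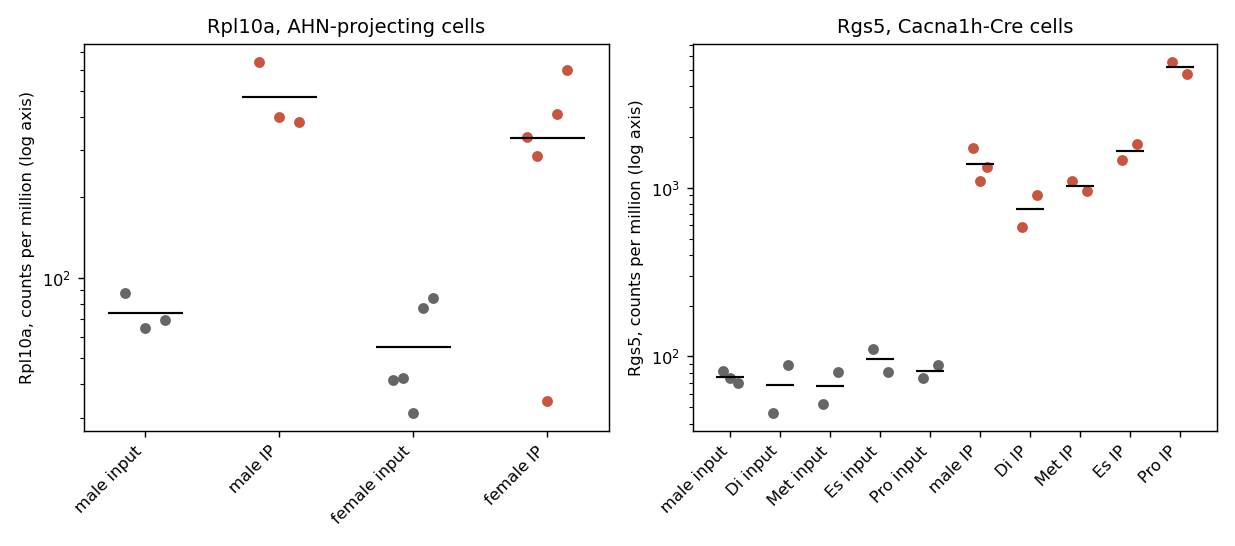
Levels of Rpl10a in the 16 AHN libraries (left) and of the pericyte gene Rgs5 in the 22 Cacna1h libraries (right), in CPM on log axes, with a point per library and bars at the group means. Rpl10a lay at 34.6 CPM in AHN female IP replicate 3 and at 285 to 643 CPM in the other AHN IP libraries. Rgs5 lay at 4760 to 5600 CPM in the Pro IP libraries, 586 to 1810 CPM in the other Cacna1h IP libraries and 46 to 111 CPM in the inputs.

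The same question was put to cells tagged through Cacna1h. These pull-downs carried large amounts of RNA of vascular mural cells, the pericytes and smooth muscle cells of vessel walls, besides RNA of deep-layer and striatal-type neurons. Rgs5, a regulator of G-protein signalling in pericytes, stood at 1942 ± 1640 CPM in IP (n = 11) and 76.9 ± 18 CPM in input (n = 11), a log2 difference of 4.35 (SE 0.13, adjusted p = 6.49e-19). Abcc9, a subunit of the potassium channel of mural cells, rose by 4.27 (SE 0.32), the adhesion protein gene Vtn by 3.83 (SE 0.16) and the receptor gene Pdgfrb by 2.37 (SE 0.20). The oligodendrocyte gene Ermn, at 15.8 ± 5.07 against 99.4 ± 21.3 CPM, and the complement gene C1qb of microglia, at 1.58 ± 1.84 against 15.2 ± 5.42 CPM, were lower in IP. Of 16153 genes tested 4569 passed, 2294 higher and 2275 lower in IP, of which 428 were at least 2-fold higher and 1057 at least 2-fold lower.

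Of 16 endothelial and mural genes 10 rose and 0 fell (10 adjusted over the list alone), with a median log2 difference of 2.37 and a camera adjusted p of 1.17e-08 (adjusted p = 0.0893 with an estimated correlation). Several genes with the largest differences had nearly no counts in input, so levels are given. Higd1b was at 31.6 ± 33.4 CPM in IP and 0.649 ± 0.474 in input, and Cox4i2, an isoform of a cytochrome oxidase subunit, at 27.3 ± 24.5 and 0.695 ± 0.957 CPM. Ndufa4l2 was at 22.6 ± 18.8 and 0.627 ± 0.889 CPM, and Pou2af1, a transcriptional coactivator, at 16.9 ± 15.3 and 0.0191 ± 0.0633 CPM. Gper1, which encodes a membrane oestrogen receptor, stood at 19.3 ± 17.4 CPM in IP and 1.33 ± 1.71 CPM in input (log2 3.92, SE 0.43, adjusted p = 4.26e-07). The heat shock gene Hspb1 rose by 3.89 (SE 0.38), and of 10 heat shock genes 7 rose and 1 fell (8 adjusted over the list alone, camera adjusted p = 0.00500, adjusted p = 0.117 with an estimated correlation).

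Genes of striatal projection neurons formed another group that was higher in Cacna1h IP: 10 of 12 rose and 1 fell (11 adjusted over the list alone, median 1.04, camera adjusted p = 9.59e-06, adjusted p = 0.258 with an estimated correlation). Examples are the dopamine receptor gene Drd2 at 97.2 ± 53.0 against 34.3 ± 15.0 CPM (log2 1.29, SE 0.18) and the phosphodiesterase gene Pde10a at 584 ± 259 against 254 ± 94.7 CPM (log2 1.11, SE 0.11). Drd1 rose by 1.10 (SE 0.15). Deep-layer cortical genes rose in part: 5 of 10 genes of layer 6 corticothalamic neurons and 0 fell (6 adjusted over the list alone, camera adjusted p = 0.00500, adjusted p = 0.0974 with an estimated correlation). Hs3st4 was up by 0.72 (SE 0.11). Of 12 genes of layer 5 pyramidal tract neurons 6 rose and 0 fell (6 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.0893 with an estimated correlation). Fezf2, a transcription factor that specifies these neurons, was up by 0.64 (SE 0.11). In the upper-layer list 1 of 11 rose and 5 fell (7 adjusted over the list alone, camera adjusted p = 0.0643), with the layer 4 gene Rorb at 58.4 ± 33.2 against 160 ± 36.9 CPM. Genes of nuclear-encoded oxidative phosphorylation were higher, 61 of 82 with 0 lower (64 adjusted over the list alone, median 0.580, camera adjusted p = 1.9e-20, adjusted p = 0.117 with an estimated correlation). Atp5k, for instance, was at 117 ± 46.4 against 44.4 ± 7.02 CPM.

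Glial genes were lower here too. All 13 oligodendrocyte genes fell (13 adjusted over the list alone, median -2.18, camera adjusted p = 8.46e-13). So did 12 of 14 microglial genes (12 adjusted over the list alone, median -2.65, camera adjusted p = 3.53e-09) and 11 of 14 astrocyte genes (12 adjusted over the list alone, median -1.62, camera adjusted p = 2.26e-09). With an estimated correlation their adjusted p was 0.0893, 0.0893 and 0.110. Among 12 pan-GABAergic genes 1 rose and 7 fell (8 adjusted over the list alone, camera adjusted p = 0.0274, adjusted p = 0.182 with an estimated correlation). Cacna1h, the gene that drives the tag, rose from 35.4 ± 15.3 to 52.4 ± 12.3 CPM (log2 0.55, SE 0.15, adjusted p = 0.00836). Cacna1i rose by 0.41 (adjusted p = 0.0117), a call lost without Es input replicate 10 or Pro input replicate 1, whereas Cacna1g (54.3 ± 13.9 against 65.0 ± 20.4 CPM, adjusted p = 0.186) did not pass. Oxtr fell by 0.62 on the log2 scale (SE 0.23, adjusted p = 0.0480), a call that was lost in the fit with a replicate block, at the same log2 of -0.62. Of the 22 fits that left out 1 library, 8 called it. Esr1 (4.30 ± 3.07 against 5.00 ± 3.75 CPM) and Pgr (56.7 ± 12.4 against 66.0 ± 13.3 CPM) did not pass, at adjusted p of 0.934 and 0.136. Rpl10a was at 21.9 ± 7.11 CPM in IP and 25.3 ± 5.24 CPM in input (adjusted p = 0.422).

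**Figure D2:**
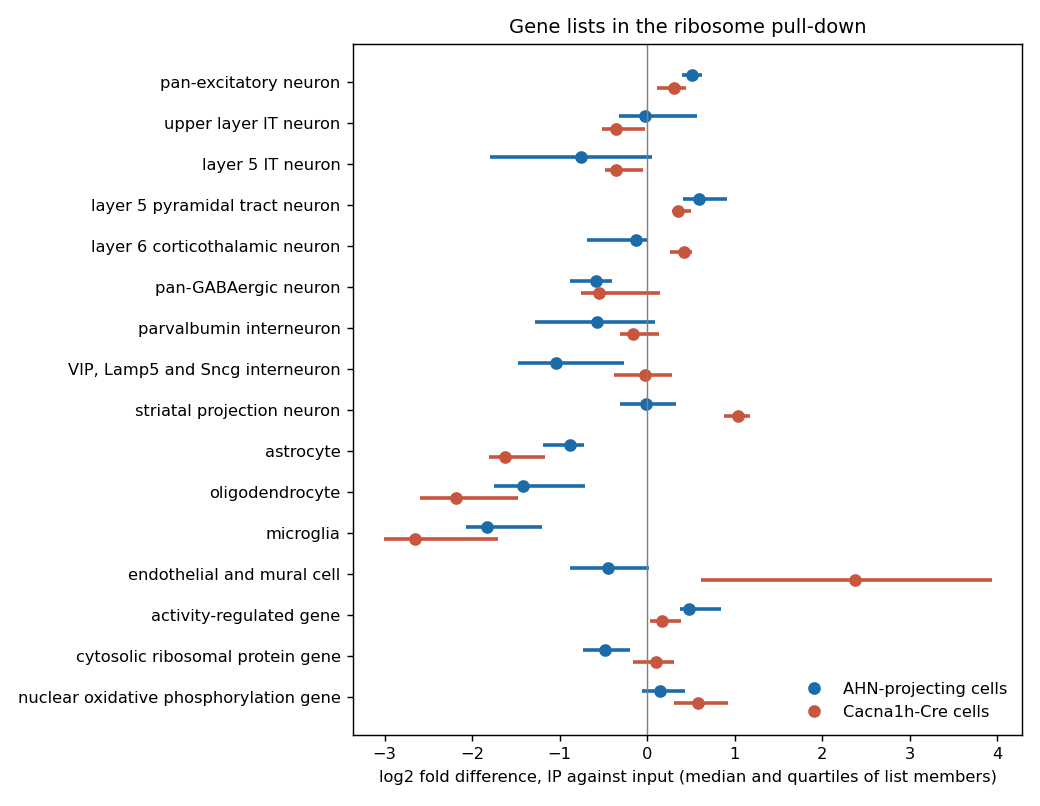
Median log2 difference between IP and input for the genes of 16 lists, with bars from the lower to the upper quartile over the genes of each list, in the AHN experiment (blue) and the Cacna1h experiment (red). The median of the endothelial and mural list was -0.447 in AHN and 2.37 in Cacna1h, and that of the microglial list -1.83 and -2.65.

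A test of the difference between the enrichments of the 2 experiments asked in which genes the tagged populations part. More mural and layer 6 corticothalamic genes were higher in Cacna1h cells, and more activity-regulated genes in AHN-projecting neurons. The differences, taken as Cacna1h minus AHN on the log2 scale, were 4.65 for Rgs5 (SE 0.19, adjusted p = 8.59e-20), 2.33 for the tachykinin gene Tac1 (SE 0.26, adjusted p = 6.85e-08), -2.0 for Nptx2 (SE 0.30, adjusted p = 1.81e-05) and -1.48 for Oxtr (SE 0.35, adjusted p = 0.00477). That of Cacna1h was -0.24 (SE 0.21, adjusted p = 0.560). Of 17141 genes tested 1651 passed, 756 higher in Cacna1h and 895 higher in AHN. The larger side turned with the scaling, since RLE factors gave 807 and 771, and DESeq2 gave 1060 and 1058. By list, 9 of 16 endothelial and mural genes (11 adjusted over the list alone) and 4 of 10 layer 6 corticothalamic genes (7 adjusted over the list alone) were higher in Cacna1h. Of 12 genes of layer 5 pyramidal tract neurons 0 were higher in Cacna1h and 1 in AHN (1 adjusted over the list alone). Of 84 ribosomal protein genes 33 were higher in Cacna1h and 1 in AHN (43 adjusted over the list alone). Of 21 activity-regulated genes 7 were higher in AHN and 0 in Cacna1h (9 adjusted over the list alone). Among 15898 genes tested in both experiments, 1172 were called higher in both (436 for independent lists of these sizes), 1258 lower in both (392 for independent lists) and 161 in opposite directions. The population, the way of tagging and the library series differ together between the experiments and cannot be told apart. Without the 5 IP libraries of highest Malat1 share (AHN female replicate 3, Es replicate 9, male replicate 18, Pro replicates 1 and 2) the count was 2519.

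The next question was whether the tagged cells differ between the sexes. In the AHN IP libraries the genes that passed were on the sex chromosomes. Xist, the RNA that silences an X chromosome, stood at 304 ± 322 CPM in females (n = 5) and 0.196 ± 0.339 CPM in males (n = 3, adjusted p = 0.00601). Female replicate 3 (library 3087) had 946 CPM of it and the other 4 females 63.2 to 284 CPM, and the call was lost without that library, male replicate 1 or male replicate 2. The Y-linked helicase gene Ddx3y stood at 0 and 48.4 ± 9.71 CPM (adjusted p = 6.65e-06). Eif2s3y, Kdm5d and Uty, also on the Y chromosome, completed the 5 genes called of 15549 tested, and 436 genes had an unadjusted p under 0.05. DESeq2 called 8 genes. The smallest adjusted p outside the X and Y chromosomes was 0.203. Cacna1h (log2 female minus male -0.20), Esr1 (-0.24), Pgr (0.12) and Oxtr (-1.03) all had an adjusted p of 1.00. In the AHN inputs the same 5 genes were called of 16384 tested, with 1301 at an unadjusted p under 0.05. DESeq2 called 59 others there, and left all 5 of these genes without an adjusted p because its filter on mean counts removed 10165 genes. A test of whether the sex difference in IP differs from that in input called 0 of 16858 genes in edgeR and 0 in DESeq2, with 509 at an unadjusted p under 0.05.

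Of 37 gene lists, 12 passed between the sexes in AHN IP under camera's preset correlation, but 4 without female replicate 3 (library 3087), which had little Rpl10a and the most Malat1. These 4 were the lists of Y-linked genes, of X inactivation and escape genes, and, lower in females, of pan-GABAergic and somatostatin interneuron genes. The AHN males are numbered 3074 to 3079 and the females 3082 to 3087 and 3090 to 3093. Sex and library series therefore cannot be told apart for the lists outside the sex chromosomes. Without library 3087 and with an estimated correlation, the camera adjusted p was 0.00589 for the Y-linked list and 0.07 for the X inactivation and escape list. The pan-GABAergic list had an adjusted p of 0.0150 (adjusted p = 0.576 with an estimated correlation) and, without library 3087, of 0.00119 (adjusted p = 0.694 with an estimated correlation). The somatostatin interneuron list had an adjusted p of 0.0231 (adjusted p = 0.386 with an estimated correlation) and, without library 3087, of 0.00333 (adjusted p = 0.501 with an estimated correlation). Astrocyte genes (median log2 0.414, adjusted p = 0.00188, adjusted p = 0.576 with an estimated correlation) did not pass without library 3087 (adjusted p = 0.0920). The same held for ribosomal protein genes (adjusted p = 1.21e-06, without the library 0.320), oxidative phosphorylation genes (adjusted p = 1.35e-06, without it 0.276) and steroid and social peptide receptor genes (adjusted p = 0.0477, without it 0.154). With an estimated correlation these 3 had an adjusted p of 0.594, 0.594 and 0.386. Apart from the Y-linked genes and Xist, no member of these lists passed on its own in edgeR. The lists of ribosomal protein and oxidative phosphorylation genes were lower in the female inputs under camera (adjusted p = 3.07e-10 and 4.03e-05, with an estimated correlation 0.806 and 0.889). No gene of these lists passed on its own there.

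In Cacna1h IP the sexes, with the stages pooled, differed in the same 5 genes: Xist (180 ± 149 CPM in 8 female and 0.646 CPM in 3 male libraries, adjusted p = 0.0228), Ddx3y (0 and 27.2 CPM), Eif2s3y, Kdm5d and Uty, of 14261 tested. The call of Xist was lost without any 1 of the 3 males, Es replicate 10 or Pro replicate 1. An unadjusted p under 0.05 was reached by 311 genes, and DESeq2 called 5. Cacna1h differed by -0.14 on the log2 scale (adjusted p = 1.00). In the inputs Erdr1, annotated on the X chromosome, was called besides these 5, at 52.5 ± 8.92 CPM in females and 23 ± 4.83 CPM in males (log2 1.19, SE 0.22, adjusted p = 0.0297). The call of Erdr1 was lost without any 1 of the 3 male inputs, Met replicate 12, Es replicate 9 or Pro replicate 2. As a list, activity-regulated genes were higher in females in IP (camera adjusted p = 3.59e-05, adjusted p = 0.411 with an estimated correlation) and in input (camera adjusted p = 3.53e-05, adjusted p = 0.696 with an estimated correlation). The list of ribosomal protein genes was higher in females in IP (camera adjusted p = 4.98e-05, adjusted p = 0.941 with an estimated correlation) and lower in input (camera adjusted p = 0.00208, adjusted p = 0.844 with an estimated correlation). No gene of these lists passed on its own in either fraction. The test of the sex difference between IP and input called 0 of 15609 genes in edgeR and 0 in DESeq2, with 274 at an unadjusted p under 0.05. Across 13590 autosomal genes measured in IP in both experiments, 12 had an unadjusted p under 0.05 in both (7.69 for independent lists), of which 4 had the same sign.

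The last question was whether the ribosome-bound RNA of Cacna1h cells varies with the estrous stage. Differences were found, and they were almost all in the Pro libraries. Pericyte genes such as Rgs5, Vtn and Abcc9 were higher, and the striatal-type genes Drd2 and Pde10a lower, in both Pro pull-downs than in each of the other 9 IP libraries. Rgs5 averaged 733 CPM in Di, 989 in Met, 1595 in Es and 4970 in Pro (n = 2 each), with 1331 in males. In the scaling of the single libraries its mean in Pro was 5177 CPM. It was higher in Pro than in the mean of the other stages by a log2 of 2.24 (SE 0.19, adjusted p of the 4-stage test = 2.78e-04). Drd2 averaged 81.2 CPM in Di, 147 in Met, 85.2 in Es and 21.3 in Pro, a log2 difference of -2.25 (SE 0.35, adjusted p = 0.0122). The stages are those of the sample titles, and the column headers of 7 files give another one, with Pro IP replicate 1 headed E and Pro IP replicate 2 headed Di. Of 14769 genes tested 432 differed between the stages. Of these 334 were highest and 88 lowest in Pro, so that 97.7% of them had an extreme there. Each gene has an extreme in 2 of the 4 stages, and Di had one in 58.3% of the genes (14 highest, 238 lowest). DESeq2 called 1834 genes. With edgeR the count was 2236 without the filter on low counts, 1071 with all 22 libraries and 895 with the 8 females. Without both Pro IP libraries, the test over Di, Met and Es called 0 genes in edgeR, with 1073 at an unadjusted p under 0.05.

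Of 16 endothelial and mural genes 5 passed, all higher in Pro (8 adjusted over the list alone, median 1.74 over the list). Abcc9 rose by 2.20 and Vtn by 1.79. Gper1 was the 1 of 14 steroid and social peptide receptor genes that passed (1 adjusted over the list alone), at 7.34, 13.2, 14.4 and 50.7 CPM in Di, Met, Es and Pro (adjusted p = 0.0209). The stages had the same order for Rgs5, and whether Gper1 changed beyond the mural genes was not tested. Of 12 striatal projection neuron genes 9 passed, all lower in Pro (11 adjusted over the list alone, median -1.58), among them Pde10a by -1.37 (SE 0.21), the enkephalin gene Penk by -1.59 and the sodium channel subunit gene Scn4b by -1.72. Tac1 was lower by -2.15 (adjusted p = 0.0139). The largest increases included Rflna, at 27.4 CPM in Pro and 0.420 to 1.31 CPM in the other stages (adjusted p = 0.00102), Tnc, an extracellular matrix gene, at 12 CPM in Pro, and the leukocyte gene Cd53 at 10.8 CPM in Pro. The gene of gonadotropin-releasing hormone, Gnrh1, stood at 1.02, 6.71, 10.3 and 0.106 CPM in Di, Met, Es and Pro (adjusted p = 0.0261). Without Pro replicate 1 the calls of Gper1, Scn4b, Tac1, Cd53 and Gnrh1 were lost, those of Gper1 and Gnrh1 also without either Di library, and those of Scn4b and Penk without Met replicate 12.

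Lists of other cell types had positive median differences in Pro, though few of their genes passed. Astrocyte genes had a median log2 difference of 1.27 between Pro and the other stages (0 of 13 passed, 6 adjusted over the list alone), and oligodendrocyte genes 0.917 (0 of 13, 4 adjusted over the list alone). For fibroblast genes it was 1.83 (1 of 9, 4 adjusted over the list alone), and for oligodendrocyte precursor genes 1.82 (1 of 6, 3 adjusted over the list alone). The precursor gene that passed was the proteoglycan gene Cspg4, which pericytes express too, at 9.85, 21.2, 31.9 and 75.9 CPM in Di, Met, Es and Pro, and its call was lost without Pro replicate 1 or any 1 of the Di and Met libraries. Oxidative phosphorylation genes had a median of -0.760 (1 higher and 4 lower of 81, 28 adjusted over the list alone). Malat1 was at 5340 and 5600 CPM in the Pro IP libraries, above the 411 to 4337 CPM in the IP libraries of the other stages. In males it was at 5753 CPM in replicate 18 and at 1621 and 1729 CPM in the others. Among the females, a high Malat1 level and Pro are thus hard to tell apart. The 4 Cacna1h IP libraries of highest Malat1 share were also the ones numbered from 3094 to 3101: Pro replicates 1 and 2, Es replicate 9 and male replicate 18. Their shares were 0.428% to 0.583%, against at most 0.195% in the others. These libraries also had the highest Vtn and Abcc9 and the lowest Drd2 of the 11 IP libraries. This did not hold for Rgs5 and Pde10a. Xist was at 56.0, 88.3, 186 and 389 CPM in Di, Met, Es and Pro (adjusted p = 0.0496). Of the 11 fits that left out 1 library, 4 called Xist. With the glial score of each library as a covariate 7 genes were called, and with its Malat1 level 2. Over the 432 genes, the median log2 difference between Pro and the other stages, signed by the fit without a covariate, was 1.78 (median SE 0.317) in that fit, 1.37 (0.381) with the glial score and 1.08 (0.497) with Malat1, so that the differences shrank and lost precision. For Rgs5 it was 2.24 (SE 0.19), 2.11 (SE 0.24) and 1.76 (SE 0.29), and for Vtn 1.79 (SE 0.26), 1.21 (SE 0.26) and 0.77 (SE 0.31). The direction stayed in all 432 genes with the glial score and in 428 with Malat1. The count also rested on single libraries. It fell to 65 without Pro replicate 1, 101 and 152 without Di replicates 1 and 2, and 120 and 137 without Met replicates 12 and 16. It rose to 1036 without male replicate 18, 1020 without Pro replicate 2, 797 without male replicate 2 and 684 without Es replicate 9.

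**Figure D3:**
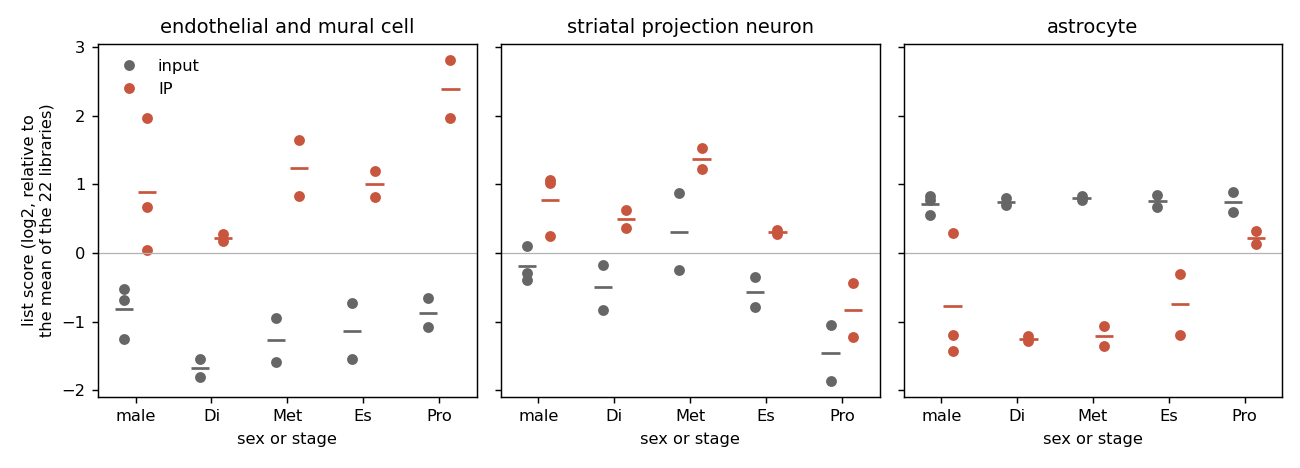
Mean log2 level of 3 gene lists in each of the 22 Cacna1h libraries, relative to the mean of all of them, with inputs in grey, IP libraries in red and a point per library. The endothelial and mural cell list lay at 1.96 and 2.81 in the Pro IP libraries, at 1.96 in male IP replicate 18 and from 0.0392 to 1.65 in the other 8. The striatal projection neuron list lay at -0.437 and -1.22 in Pro IP and from 0.246 to 1.53 in the other 9, and the astrocyte list lay at 0.127 and 0.323 in Pro IP and 0.298 in male IP replicate 18.

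Unlike Gper1, the receptor genes Esr1, Pgr and Oxtr did not pass the stage test in IP, nor did the tag's own driver gene. Cacna1h averaged 39.4 CPM in Di, 40.9 in Met, 69.7 in Es and 46.0 in Pro (adjusted p = 0.124), and Esr1, Pgr and Oxtr had adjusted p of 0.771, 0.458 and 0.364. Between Es and Di, the stages of high and low sexual receptivity, Cacna1h differed by 0.82 on the log2 scale (SE 0.25, adjusted p = 0.514), 69.7 against 39.4 CPM. That comparison called 0 genes in edgeR, with 1268 at an unadjusted p under 0.05 and 64 calls in DESeq2. Without the filter on low counts edgeR called 147 genes, 135 higher and 12 lower in Es. The endothelial and mural list was higher in Es than in Di under camera (adjusted p = 0.0176, adjusted p = 0.841 with an estimated correlation), with 0 of its 16 genes passing (5 adjusted over the list alone). Malat1 lay at 4337 and 2087 CPM in Es IP and 411 and 1089 CPM in Di IP. Against males, Di, Met and Es each gave Xist and the 4 Y-linked genes alone in edgeR, whereas DESeq2 called 8, 5 and 22 genes. Without the filter on low counts edgeR called 41, 17 and 53. With the filter, the edgeR count fell to 3 for Di without male replicate 1 or either Di library, and to 2 for Met without male replicate 1 or either Met library. For Es it fell to 2 without male replicate 1 or Es replicate 9 and to 3 without male replicate 18, and rose to 11 without male replicate 2. Pro gave 347 genes in edgeR, 220 higher and 127 lower, of which 342 were other than these 5, and 1375 in DESeq2. These included Rgs5 (4970 ± 660 CPM in Pro and 1331 ± 283 CPM in males, log2 1.90, SE 0.22, adjusted p = 7.02e-04), Gper1 (log2 2.18, SE 0.44), Drd2 (-2.49, SE 0.38) and Penk (-1.99, SE 0.33). The call of Gper1 was lost without male replicate 1 or 2 or Pro replicate 1, and that of Penk without male replicate 1. The count for Pro fell to 18 and 58 without male replicates 1 and 2, to 42 without Pro replicate 1, to 168 without either Di library and to 153 and 155 without Met replicates 12 and 16. It rose to 1696 without Pro replicate 2 and 1681 without male replicate 18. All these contrasts share the 3 male libraries.

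In the inputs of the same mice the stages differed in 1 gene of 15585, Tmem59l, at 274 CPM in Di, 104 in Met, 90.1 in Es and 91.3 in Pro (adjusted p = 0.0142). An unadjusted p under 0.05 was reached by 1537 genes, and DESeq2 called 199. Tmem59l was not called without Di replicate 2. That count was 48, 26, 30, 37 and 30 without Di replicate 1, Di replicate 2, Met replicate 16, Pro replicate 1 and Pro replicate 2. It was 6 without Met replicate 12, 3 without Es replicate 10 and 2 without male replicate 1. Of 12 striatal projection neuron genes 0 passed in input (10 adjusted over the list alone), with a median log2 difference of -1.06 between Pro and the other stages. Drd2 lay at 17.4 and 20.9 CPM in the Pro inputs and at 19.8 to 65.4 CPM in the other inputs.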

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

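Of the tests in this part, the one of untagged RNA by its IP to input direction, the interaction test of the enrichments and the counts over regrouped libraries were planned. All others were chosen only after the results they examine had been seen, as were the genes screened for single libraries far from their group.

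The first pattern is that the genes that differ between stages in Cacna1h IP rest on Pro. RNA of untagged cells carried into the Pro pull-downs would raise genes low in the other IP libraries and lower genes high there. This stays open: 88 of the 89 genes lower in Pro had a positive IP minus input difference in those libraries. However, so did 52.9% of the 342 genes higher in Pro (exact 95% interval 47.5 to 58.3) and 49.5% of all genes tested. The genes were picked partly by these same libraries, which favours the outcome that untagged RNA predicts. In a second test, 57.1% of the 343 genes higher in Pro lay above their level in the Pro inputs (exact 95% interval 51.7 to 62.4). The bound was an adjusted p under 0.05, and by it 2 genes lay below the inputs. RNA like that of the Pro inputs as the whole source would not raise a gene above those inputs. The 343 genes were picked by the same Pro IP libraries, which raises this share, so it argues only weakly against that source. More vessel tissue in the Pro pieces is weakly argued against, because 8 mural genes differed by -0.165 (SE 0.34) on the log2 scale between Pro and other inputs and by 1.60 (SE 0.44) in IP. The test asked for a fixed part of the IP difference in the inputs. Their difference minus that part was -0.963 (SE 0.40), only a little past the bound of 2 SE. Less striatal tissue stays open for the striatal part, because 12 genes differed by -1.22 (SE 0.38) in input and -1.57 (SE 0.29) in IP. The inputs of Di replicate 1 and Es replicate 10 were about as low in Drd2, at 19.8 and 22.2 CPM, as the Pro inputs, at 20.9 and 17.4 CPM. Their IP libraries nevertheless had 77.6 and 104 CPM, against 27.4 and 16.8 CPM in Pro. Pde10a went the same way, so less tissue alone may not account for the fall of these genes in IP. The library series 3094 to 3101 cannot be told apart from the stage: of the other 2 IP libraries in it, Es replicate 9 moved by 0.152 and male replicate 18 by 0.458 of the Pro difference, and the stage itself stays among the open explanations.

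The second pattern is that AHN female IP replicate 3 (library 3087) lacks the Rpl10a signal. An input library with an IP label is argued against, because the slope of its difference from the inputs on the male IP minus input difference was 0.504 over 7182 genes, against -0.0653 to 0.110 in female inputs and 0.777 to 0.874 in the other female IP libraries. The bound for this test was changed after that slope was seen, and the first bound was a slope over 0.5. Little tagged ribosome in the tissue stays open as a candidate explanation. The slope was below that of the other 4 female IP libraries. These, unlike library 3087, had helped to pick the 7182 genes, which favours this order. The same-numbered input (library 3084) had rank 1, the lowest Rpl10a level of the 8 AHN inputs. However, female inputs 3082 and 3083 were low too, at 41.6 and 42.1 CPM, against 64.7 to 87.9 CPM in the remaining inputs. Female IP libraries 3085 and 3086 still had 336.5 and 285.3 CPM, so the rank is weak support. The replicate numbers are also not shown to pair the AHN samples (the deviations of libraries 3084 and 3087 correlated at 0.02). No biological explanation was tested.

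The third pattern is that mural genes are over-represented in Cacna1h IP. Vessel fragments carried into the pull-down are argued against, because the median of 8 mural genes exceeded that of 8 endothelial genes by 3.47 on the log2 scale (4.05 against 0.580, exact two-sided permutation p = 0.00311 over genes, which are not independent). Vessel RNA bound without the tag is only weakly argued against. The median of the mural genes in AHN IP was -0.474, and the highest of them there, 0.908, lay below the lowest in Cacna1h IP, 2.37. However, the 8 mural genes were set apart after the Cacna1h result was seen, which favours this order. The experiments also differ in tagging and library series, so untagged background may differ between them. That mural cells themselves carry the tag in this Cre line remains a hypothesis, found on the same data, and Cav3.2 is known from vascular smooth muscle.

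Only the female AHN IP and female AHN input groups, with 5 libraries each, were screened for single libraries far from the rest. The other groups, among them all of the Cacna1h experiment, are smaller and were not screened. Of 93 combinations of group and measure 12 were past the bound, where chance gives about 1 in 20. Many of the 12 are of library 3087 and are not independent, so this rate is a rough guide only. Of the 12, Uty and Ddx3y rest on 1 count against 0 in the other libraries, which passes the test by construction and tells nothing. In the female AHN IP libraries, library 3087 had 1.21% Malat1 (0.088 to 0.412 in the other 4), 481 CPM of Cdr1 (154 to 214), and 5860 CPM of Camk2a (3370 to 3750). It also had 1010 CPM of Cacna1e (530 to 588), 97.5 CPM of Rgs5 (55.2 to 62.4), 946 CPM of Xist (63.2 to 284) and 0.0451 CPM of Uty (0 in the others). Library 3092, another female AHN IP library, had 0.129 CPM of Crh (0.393 to 0.468). In the female AHN inputs, library 3084 had 0.694% Malat1 (1.04 to 1.18), library 3082 had 6.80 CPM of Chst8 (5.79 to 5.85) and 23.9 CPM of P2ry12 (12.5 to 15.3). Library 3083 had 0.0237 CPM of Ddx3y (0 in the others).

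The enrichments of the 2 experiments differed by the interaction test in 1651 genes. Besides Rgs5 (4.65), Tac1 (2.33), Nptx2 (-2.0) and Oxtr (-1.48), the log2 differences, Cacna1h minus AHN, were 4.73 for Vtn, 4.48 for Abcc9, 2.28 for Pvalb, 2.23 for Vip, 1.69 for Hs3st4, and 0.987 for Pde10a. They were -1.19 for Bdnf, -1.60 for Wfs1 and -2.83 for Rpl10a. Ifitm1 differed by 8.99, a fitted value that depends on few counts, with 10.3 CPM in Cacna1h IP and 0.321 in input against 0.114 CPM in AHN IP and 1.87 in input.

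Regrouping the libraries tested whether chance could give counts as large. For AHN IP against input 1 of 100 splits, the real one, gave 6039 genes, and the highest other gave 2429. For Cacna1h IP against input 1 of 60 splits gave 4569 (highest other 1904). For the difference of the enrichments, in a simpler fit of 4 groups, 1 of 30 splits gave 1281 (highest other 1). The numbers 60 and 30 were set by the limit on computing time. Chance can be excluded for the 2 comparisons of IP against input. The other splits of the enrichment test mix libraries of both experiments within each group. Differences between the experiments then count as spread, so low counts in these splits were fixed beforehand and do not decide on chance. Between the sexes, as many genes came from 2 of 56 splits in AHN IP (real 5, highest other 33), and 4 of 56 in AHN input (real 5, highest other 34). As many came from 4 of 100 in Cacna1h IP (real 5, highest other 3020) and 4 of 100 in Cacna1h input (real 6, highest other 219). The share of splits lay under the bound set beforehand for excluding chance in all but AHN input, although single other splits gave more genes than the real one in each. The count does not take into account which genes were called, so it does not decide on chance for Xist and the Y-linked genes. The 5 genes of AHN input are Xist and Y-linked genes, the smallest adjusted p among them being 1.18e-14. The split with 3020 genes set male replicate 18 and both Pro libraries against the rest, and that with 219 set both Di libraries and Met replicate 12 against the rest. Both point to a structure of the samples other than sex. For the interactions of sex and fraction, with 0 genes, 56 of 56 splits (AHN, highest other 2) and 100 of 100 (Cacna1h, highest other 459, from male replicate 18 and both Pro libraries) gave as many. A real count of 0 fixes this outcome, so it tests nothing.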

How the results depend on the processing

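Of the alternatives here, the covariates, the stages of the column headers, the stage test without both Pro libraries and the fits without libraries picked for their Malat1 or Rpl10a level were chosen after seeing the data. Under RLE factors each count stayed within 1.5 times the reported one, and the median of all genes shifted by under 0.03. With a 2-fold minimum, AHN IP against input gave 1892 genes (337 higher, 1555 lower) and Cacna1h IP against input 1485 (428 and 1057). DESeq2 called 8 genes for sex in AHN IP, 59 in AHN input, 1834 for stage in Cacna1h IP, 64 for Es against Di, 8 for Di, 22 for Es and 1375 for Pro against males, and 199 for stage in input. No filter on low counts gave 2236 for stage, 147 for Es against Di, 41, 17, 53 and 1633 for Di, Met, Es and Pro against males, and 348 for stage in input; more genes were tested there. The stage test gave 1071 with all 22 libraries, 895 with the 8 females, 0 without Pro, 7 with the glial and 2 with the Malat1 covariate, and Pro against males 115 and 24 with these covariates. The input stage test gave 3 with all 22 libraries, the enrichment difference 2519 without 5 IP libraries, and the list tests 7 with an estimated correlation. The list tests of sex in AHN IP gave 4 without library 3087. The cause was not tested in any of these. Es against Di by the headers' stages gave 0.

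Leaving out 1 library at a time gave 4971 to 7186 genes for AHN IP against input, 4 to 6 for sex in AHN IP, 5 to 7 in AHN input and 0 to 0 for the interaction. It gave 3862 to 4795 for Cacna1h IP against input, 4 to 5 for sex in IP, 5 to 6 in input and 0 to 0 for the interaction. The range was 65 to 1036 for stage in IP, 1 to 48 in input, and 0 to 0 for Es against Di. It was 3 to 5, 2 to 5, 2 to 11 and 18 to 1696 for Di, Met, Es and Pro against males. A lone library left in a group is assumed to vary like the other groups. With the replicate block, AHN IP against input gave 6332 genes, Cacna1h IP against input 4489, sex in AHN IP 6 and in AHN input 6, and the interactions 0 and 0. For sex in AHN the block was the replicate number alone. It joined mice of both sexes that share a number and is not a block for the animal. In AHN IP against input and the AHN interaction, the block joined the different female mice that share number 1 or 2. The block ended the calls of Batf3 in AHN and of Sst, Tmem212 and Oxtr in Cacna1h IP against input and added that of Esr1 in AHN. It changed no other call of a named gene in these 6 comparisons and was not fitted to the others. In the AHN experiment the numbers are not shown to pair the samples: over 12 possible pairs the correlations were -0.0494 to 0.234, and 4 libraries matched best with their own number. Some of these pairs must join different mice, because numbers 1 and 2 repeat among the females. With female libraries 3082 to 3087 and 3090 to 3093 taken as separate sets, pairs within a set or among males had -0.0117 to 0.234. Pairs across the sets had -0.0494 to 0.0297.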

Other observations

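The tests of Xist and Malat1 in this part were chosen only after their levels had been seen; the list tests were planned. Signalling genes that the report did not describe also differed between IP and input. In AHN IP 11 of 22 glutamate receptor genes rose and 3 fell (16 adjusted over the list alone, camera adjusted p = 0.0476, adjusted p = 0.550 with an estimated correlation). The NMDA receptor gene Grin1 rose by 0.83 on the log2 scale (SE 0.11) and the metabotropic receptor gene Grm3 was at -0.49 (SE 0.10). Of 10 heat shock genes 6 rose and 1 fell (7 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.337 with an estimated correlation), the chaperone gene Hsp90aa1 by 0.98 (SE 0.08, adjusted p = 1.64e-08). Neuropeptide genes went both ways, 6 up and 6 down of 18 (13 adjusted over the list alone, camera adjusted p = 0.631). The enkephalin gene Penk rose from 41.5 ± 14.3 to 109 ± 24.9 CPM and Adcyap1, which encodes the peptide PACAP, from 26.0 ± 5.47 to 66.6 ± 22.6 CPM (n = 8 each). In the somatostatin list 3 of 8 genes rose and 2 fell (6 adjusted over the list alone), with Nos1, the neuronal nitric oxide synthase gene, up by 1.13 (SE 0.14) and Sst at -0.78 (SE 0.17).

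In Cacna1h IP 5 of 8 voltage-gated sodium channel genes rose and 0 fell (5 adjusted over the list alone, camera adjusted p = 0.0549), among them Scn4b by 0.97 (SE 0.14). Of 3 red blood cell genes 2 fell (3 adjusted over the list alone, camera adjusted p = 0.00500, adjusted p = 0.117 with an estimated correlation). Of 6 choroid plexus and ependymal genes 3 fell (4 adjusted over the list alone, camera adjusted p = 0.0497, adjusted p = 0.249 with an estimated correlation). Sncg rose by 2.35 (SE 0.49, adjusted p = 5.07e-04), and Grik1, a kainate receptor gene, fell by 1.83 on the log2 scale (SE 0.24). Neurosteroid enzyme genes gave 0 calls of 9 in edgeR (0 adjusted over the list alone, camera adjusted p = 0.727).

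Across the 8 female Cacna1h IP libraries, Xist rose with Malat1: Pearson's r was 0.987 (exact permutation p = 2.48e-05, adjusted p = 4.96e-05 over both coefficients) and Spearman's rho 1 (exact permutation p = 4.96e-05). The coefficient r was 0.981 without the 2 libraries farthest from the median. The hypothesis that nuclear RNA of the input kind was carried into the pull-downs first passed on this correlation alone. It would keep the ratio of both RNAs at its value in input, but the ratio of Xist to Malat1 was 5.43% to 8.33% in these IP libraries and 0.167% to 0.891% in the female inputs, which argues against it. No correlation was computed over the 5 female AHN IP libraries, in which Xist was at 63.2, 151, 198, 284 and 946 CPM where Malat1 was at 940, 1243, 2166, 4246 and 13670 CPM.

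The column headers of 7 files name another estrous stage than the sample titles: Met replicate 12 is headed E in both fractions, Met replicate 16 Di in both fractions, Pro replicate 1 E in IP, and Pro replicate 2 Di in both fractions.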
